A study of Rattus norvegicus with 82 samples.

How the data were processed

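Heart RNA from male Wistar rats was measured on 82 Affymetrix arrays. Per the labels, animals received 1 intravenous dose of vinblastine, vincristine, colchicine or 0.9% saline. Hearts were taken 6 or 24 h later. Total RNA was purified with Qiagen RNeasy and turned into biotinylated cRNA with the Affymetrix 3' IVT express kit, per the labels. Each array comes from 1 animal, and there are 14 groups of 5 or 6 animals. The labels give a replicate number within each group, and no file or label places an animal in a litter, batch or day.

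The deposited table holds intensity values on a linear scale, which the authors normalized between arrays and summarised per probe set. The summarisation method was not given in the sources used here. The values ran from 9.76 to 39497, and the median intensity per array ran from 57.6 to 63.3. The mean correlation of an array with the others of its group lay between 0.967 and 0.996. No raw scan was used, so the precision rests on the number of arrays per group. The number of columns belonging to other samples was 0.

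The deposited values covered 31099 probe sets, of which 57 were control probe sets. Gene symbols came from the annotation of the array: 20826 probe sets carried 1 symbol, 436 carried several and 9831 were not in it. The rat genome tables (GRCr8) were used for names only. The 20826 probe sets covered 14217 symbols, and 4525 genes had more than 1 probe set. The probe set with the highest mean over all arrays stood for its gene. Because the values are linear, 16 was added before taking log2, which damps the noise of dim probe sets. A gene was tested where its probe set was above the 40th percentile of its array on at least 5 arrays, which left 11319 genes. Probe sets with no symbol or several symbols were counted in a separate fit.

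Group means were fitted to all 82 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (residual df 68, prior df 4.7) and data.table (version 1.17.8) for reading. The fit gave 30 comparisons. Of these, 12 set a dose against the vehicle of the same time and 6 set the higher dose against the lower. A further 6 set compounds against each other at their higher dose, and 2 set vinblastine against vincristine at their lower dose. The last 4 dealt with time: the change at 24 h minus the change at 6 h for each compound at its higher dose, and vehicle at 24 h against vehicle at 6 h. P values were adjusted by the Benjamini-Hochberg method over the 11319 genes of a comparison, and the threshold was an adjusted p under 0.05. Errors given with log2 changes are standard errors of the model, and those given with intensities are standard deviations.

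Gene lists, 36 in number, were written before the data were examined. Each was tested with camera in limma at its preset correlation of 0.01 between genes and adjusted over the 36 lists. The same test with a correlation estimated from the residuals was run as an alternative. For each list the members past the threshold were counted, both with the adjustment over all genes and with an adjustment over the list alone. Listed genes that were absent from the array or under the filter are not part of these numbers. A gene bright only in treated groups could pass the filter.

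Genes were named by a rule written before the data were examined. For a higher dose against vehicle it took the 6 largest rises and 6 largest falls past the threshold in which every treated animal lay on the same side of the vehicle mean. For these, 6 of 6 follows from the rule. Up to 3 members of each list past the threshold were added, those with the largest change. For the other comparisons it took the 3 largest rises and 3 largest falls past the threshold. Symbols beginning with LOC or RGD were counted and not named, and some genes that the rule takes were left out for length or are not reported here. Other genes appear only where the text says that they were chosen after the values were seen.

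The distance of each array to the median profile of its own group, without that array, and to the median profile of every other group was the root mean square difference in log2. Where the distance to the own group was more than 1.3 times that to another group, the array was set apart as lying nearer another group. This held for 10 arrays, and another 35 lay nearer to another group by a smaller ratio. Leaving the 10 out is an alternative chosen after the data were examined, and all 82 arrays as labelled remain the basis of every leading value.

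Comparisons of compounds within a time share their vehicle animals, which makes 2 changes correlate without any shared effect. The excess was gauged with 100 simulations in which treated groups had no effect, with separate sets of 3 vehicle animals for each compound in 20 splits, and with the number of shared calls that independent lists would give. Chance groupings were gauged by refitting each comparison with 100 regroupings of its arrays, the real one included.

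The code was tested on simulated data, with 200 genes given an added change in each of 10 rounds. At log2 changes of 0.5, 1 and 2 it recovered 85.4%, 98.2% and 100% of the genes for vinblastine 3 mg/kg at 6 h, with 5.3% false calls. For vincristine 0.1 mg/kg at 24 h, with 5 arrays, it recovered 84.2%, 99.1% and 100% with 4.9% false calls. The sign was wrong for 0 genes. A shifted list was found in 10 of 10 rounds and an unshifted list in 0. The simulated genes varied independently of each other, so this does not test list calls where genes vary together.

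Alternatives written before the data were examined were quantile normalization, centring of the arrays, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, and offsets of 1 and 64. The same holds for the replicate number as a block, leaving out 1 array at a time and leaving out the 6 arrays whose descriptions end in _2. A mean-variance trend with robust variances, array weights, every probe set on its own, a fit of only the groups compared and an estimated correlation for the lists complete that set. The closing section gives their effect. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.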

Results

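Gene expression was compared in the hearts of 82 male Wistar rats, 6 or 24 h after 1 intravenous dose of a compound that binds tubulin or of saline. Vinblastine was given at 0.5 and 3 mg/kg, vincristine at 0.1 and 1 mg/kg and colchicine at 0.2 and 2 mg/kg. Each group had 6 animals, except the vincristine 0.1 mg/kg groups with 5 each. The number of arrays per group limits the precision. Of 11319 genes tested, 566 would be under an unadjusted p of 0.05 by chance in any comparison.

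All results use the arrays as labelled. On 10 arrays, however, the profile lay nearer to that of another group than to its own by a ratio over 1.3. At 6 h these were the arrays labelled vinblastine 0.5 mg/kg replicate 6, vinblastine 3 mg/kg replicate 1, vincristine 1 mg/kg replicate 3, colchicine 0.2 mg/kg replicates 1 and 6 and colchicine 2 mg/kg replicate 4. At 24 h they were vinblastine 0.5 mg/kg replicate 5, vincristine 0.1 mg/kg replicate 5, colchicine 0.2 mg/kg replicate 6 and colchicine 2 mg/kg replicate 1. Counts of all genes past the threshold without these 10 arrays, an alternative chosen after the data were examined, stand beside the main counts.

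**Figure D1:**
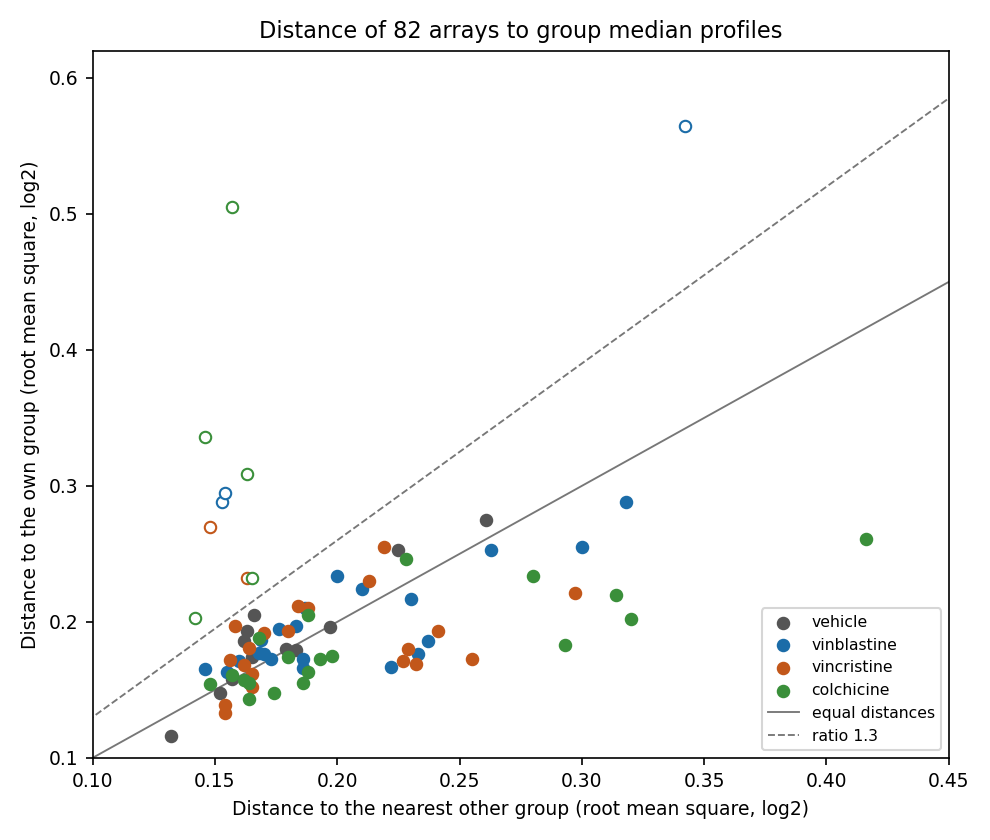
Each point is 1 array, placed by its distance to the median profile of the nearest other group (horizontal) and of its own group (vertical), with the 10 arrays over a ratio of 1.3 as open points. The farthest from its own group was the array labelled vinblastine 3 mg/kg at 6 h replicate 1, at 0.565 against 0.342 to the nearest other group.

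The comparison of vinblastine 0.5 mg/kg with vehicle at 6 h asks what a low dose does early. Transcripts of tubulin, the protein that the compound binds, fell. Tuba4a, an alpha tubulin of muscle and brain (1371542_at), decreased from 5340 ± 571 to 720 ± 87.8, 7.29-fold (log2 -2.87 ± 0.49, adjusted p = 0.00134, n = 6 against 6, all 6 animals lower). The beta tubulin Tubb4b (1371390_at) decreased from 3310 ± 436 to 655 ± 73.4 (log2 -2.31 ± 0.42, adjusted p = 0.00311, 6 of 6 animals). Tubg1, the gamma tubulin that seeds microtubules at the centrosome (1370809_at), decreased from 424 ± 44.3 to 186 ± 19.9 (log2 -1.13 ± 0.21, adjusted p = 0.00418, 6 of 6). Of 9 alpha and beta tubulins measured, 2 fell past the threshold and 8 when adjusted over the list alone, with a median log2 change of -1.07. The list held in camera at an adjusted p of 1.08e-20, and at 0.00011 with an estimated correlation. Where 2 p values follow a list, the first is that of camera, adjusted, and the second that with an estimated correlation.

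These 3 genes and Polr3b, a subunit of RNA polymerase III, made up all 4 genes past the threshold at the low vinblastine dose at 6 h. Polr3b rose from 123 ± 8.9 to 155 ± 6.48 (log2 0.3 ± 0.06, adjusted p = 0.0111, 6 of 6 animals). Its call was lost without the vehicle replicates 2 (adjusted p = 0.0631), 3 (0.0958) or 4 (0.0546), or without vinblastine replicates 2 (0.0671) or 6 (0.062). It was also lost when only the compared groups were fitted (0.266) and without the 6 arrays ending in _2 (0.269). Under an unadjusted p of 0.05 there were 590 genes, and without the 10 arrays 10 genes passed. Interferon genes moved up as a list (adjusted p = 0.000569, 0.68 with an estimated correlation) and so did proteasome genes (0.000751 and 0.781), with 0 members past the threshold in each and 1 interferon gene over the list alone.

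Vinblastine 3 mg/kg against vehicle at 6 h asks for the early response of the heart to a high dose. S100a9, a calcium-binding protein of neutrophils, rose from 59 ± 25.2 to 922 ± 208 (log2 3.68 ± 0.53, adjusted p = 2.46e-06, n = 6 against 6, 6 of 6 animals). Tnfrsf12a, the TWEAK receptor induced by injury, rose from 166 ± 21.1 to 1430 ± 250 (log2 2.97 ± 0.47, adjusted p = 5.44e-06, 6 of 6). Otud1, a deubiquitinase, rose from 473 ± 120 to 3370 ± 897 (log2 2.78 ± 0.57, adjusted p = 0.000219, 6 of 6).

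Tuba4a (log2 -2.98 ± 0.49, adjusted p = 1.1e-05), Tubb4b (-2.52 ± 0.42, 1.37e-05) and the alpha tubulin Tuba8 (-2.35 ± 0.41, 3.44e-05) fell with 3 mg/kg vinblastine at 6 h, each in 6 of 6 animals. Of the 9 tubulins 5 fell and 0 rose, and the same 5 when adjusted over the list alone (median log2 -1.41, camera adjusted p = 4.75e-06, 0.121 with an estimated correlation).

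Of 14 cardiac stress genes 11 rose with 0 falling, or 12 when adjusted over the list alone (camera adjusted p = 3.48e-08, 0.121 with an estimated correlation). Among them Nppb, the natriuretic peptide gene induced by wall strain, rose from 3350 ± 1290 to 9450 ± 1400 (log2 1.56 ± 0.33, adjusted p = 0.000274). Rcan1, a calcineurin target and feedback inhibitor, rose from 1850 ± 406 to 6960 ± 1600 (log2 1.9 ± 0.29, adjusted p = 4.43e-06). Ankrd23, a stretch-linked ankyrin repeat protein of the sarcomere, rose by log2 2.22 ± 0.44 (adjusted p = 0.000144). The matrix protein Ccn2, also called CTGF, rose from 587 ± 102 to 2740 ± 925 (log2 2.16 ± 0.4, adjusted p = 7.09e-05). All 6 treated animals showed each of these 4 rises.

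Among inflammation genes 4 of 5 measured neutrophil markers rose (camera adjusted p = 0.000266, 0.121 with an estimated correlation), 12 of 16 genes of NF-kappaB and the acute phase (5.36e-07 and 0.121) and 10 of 17 chemokines and cytokines (0.000681 and 0.226), with 0 falling. Adjusted over each list alone the numbers were 4, 12 and 11. Most of the listed neutrophil markers were not measured. Icam1, the adhesion molecule that holds leukocytes to endothelium, rose from 135 ± 18.4 to 447 ± 98.3 (log2 1.6 ± 0.24, adjusted p = 2.46e-06, 6 of 6). Ccl2, the monocyte chemoattractant, rose from 61.6 ± 14.3 to 362 ± 311 (log2 2 ± 0.35, adjusted p = 3.67e-05, 6 of 6). Endothelial activation and coagulation genes rose in 11 of 14 with 1 falling, 12 when adjusted over the list alone (camera adjusted p = 3.88e-06, 0.121 with an estimated correlation). Adamts1, a secreted protease, led them with log2 2.3 ± 0.46 (adjusted p = 0.000154, 6 of 6). By contrast 6 of 26 endothelial markers rose and 4 fell, without a shift of the list (adjusted p = 0.928).

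Growth and protein turnover genes moved as well at this dose and time. Of 18 ribosome biogenesis genes 14 rose and 0 fell, 15 over the list alone (camera adjusted p = 9.18e-07, 0.273 with an estimated correlation), and of 23 genes of proteasome and muscle atrophy 17 rose, 20 over the list alone (1.79e-07 and 0.273). Immediate early genes rose in 11 of 22, 14 over the list alone (0.000109 and 0.293), led by the stress-induced transcription factor Atf3 at log2 2.3 ± 0.47 (adjusted p = 0.000202, 6 of 6). Pdk4, which spares glucose by blocking pyruvate dehydrogenase, rose by log2 2.17 ± 0.4 (adjusted p = 7.05e-05, 6 of 6), and Ppargc1a, a regulator of mitochondrial genes, fell by 0.9 ± 0.19 (adjusted p = 0.000396, 6 of 6). With the 10 arrays left out 10 ribosome biogenesis genes rose and 1 fell, and 11 genes of proteasome and muscle atrophy, 11 immediate early genes, 10 cardiac stress genes, 10 of NF-kappaB and the acute phase, 8 chemokines and cytokines and 4 neutrophil markers rose. Of 35 oxidative phosphorylation genes 0 passed in either direction (camera adjusted p = 0.928). Of 22 mitosis genes 1 fell and 0 rose, with 0 over the list alone (0.00101, 0.308 with an estimated correlation, 0.0536 with the stricter filter).

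In all, 2637 genes passed for vinblastine 3 mg/kg at 6 h, 1769 up and 868 down, or 1463 up and 1313 down after quantile normalization. Without the 10 arrays 1160 rose and 625 fell, and the number was 1381 without vinblastine replicate 1, 1314 without the 6 arrays ending in _2 and 958 when only the compared groups were fitted. At least a 2-fold change was seen for 156 genes.

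**Figure D2:**
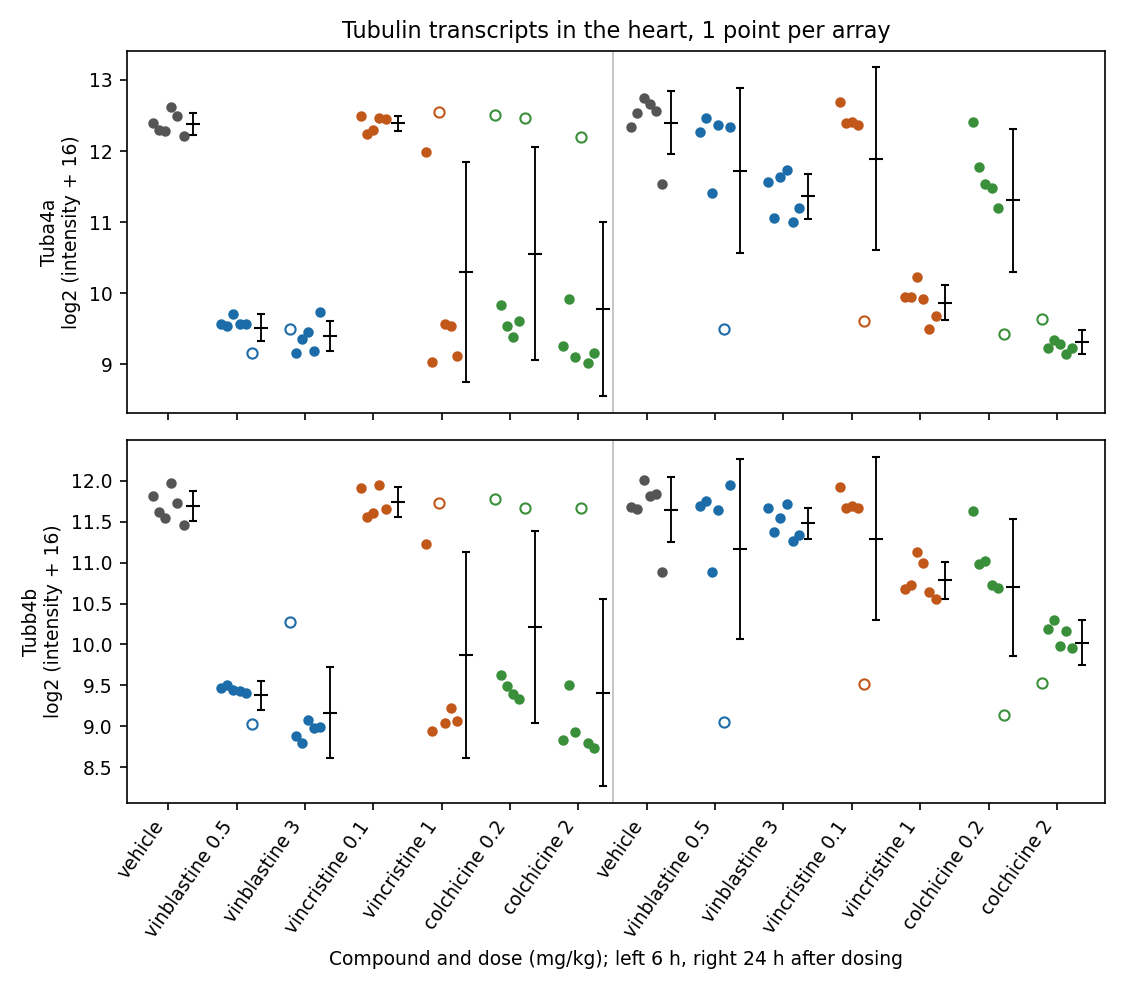
Each point is the log2 intensity of Tuba4a (top) or Tubb4b (bottom) on 1 array, with group mean and standard deviation in black and the 10 arrays as open points. In hearts labelled vinblastine 0.5 mg/kg the mean Tuba4a intensity was 720 at 6 h and 4060 at 24 h, against 5340 and 5580 in vehicle. Without the open points it was 753 and 4730.

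Vincristine 0.1 mg/kg against vehicle at 6 h, the low dose of the second compound, gave 0 genes in limma, with 440 under an unadjusted p of 0.05. Tuba4a stood at 5360 ± 411 (n = 5) and 5340 ± 571 in vehicle (n = 6). Leaving out the 10 arrays gave 1 gene, and so did quantile normalization. Immediate early genes moved down as a list (camera adjusted p = 0.00809, 0.981 with an estimated correlation).

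Vincristine 1 mg/kg against vehicle at 6 h asks for the early response to its high dose. The genes named first moved the same way in all 6 treated animals, which the rule requires of the largest changes. Fgl2, a coagulant protein of activated endothelium and macrophages, rose from 337 ± 95.3 to 978 ± 299 (log2 1.48 ± 0.33, adjusted p = 0.00991, n = 6 against 6). Stab1, a scavenger receptor of macrophages and sinusoidal endothelium, fell from 197 ± 55 to 87.2 ± 32.3 (log2 -1.06 ± 0.21, adjusted p = 0.00593). Irf1, an interferon-induced transcription factor, rose from 231 ± 36.1 to 364 ± 68.7 (log2 0.62 ± 0.12, adjusted p = 0.00593). Ndrg1, induced by hypoxia and stress, rose from 355 ± 38.4 to 557 ± 83.4 (log2 0.62 ± 0.13, adjusted p = 0.0094). Gucy1a1, a subunit of the nitric oxide receptor, fell by 0.7 ± 0.15 (adjusted p = 0.0094).

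The tubulin transcripts Tuba4a (log2 -2.09 ± 0.49, adjusted p = 0.0124) and Tubb4b (-1.82 ± 0.42, 0.0124) were lower in 5 of 6 animals given vincristine 1 mg/kg. On a log2 scale Tuba4a stood at 11.98 and 12.55 in replicates 1 and 3 and between 9.03 and 9.56 in the other 4. Both calls were lost without vincristine replicate 4 (adjusted p = 0.0666), and that of Tuba4a without replicate 5 (0.0516). The same replicate 4 ended the calls of Ccn2 (log2 1.85 ± 0.4, adjusted p = 0.0094, then 0.0586) and Nppb (1.39 ± 0.33, 0.0124, then 0.0666). Of the 9 tubulins 4 fell, 5 over the list alone (median log2 -0.94, camera adjusted p = 3.22e-05, 0.24 with an estimated correlation). Of 20 actin and SRF/YAP target genes 6 rose, 8 over the list alone (8.82e-07 and 0.211), and of 14 cardiac stress genes 4 rose, 5 over the list alone (4.47e-06 and 0.24). Of 17 markers of monocytes and macrophages 4 fell and 1 rose, 5 and 1 over the list alone (6.76e-05 and 0.24). Oxidative phosphorylation moved up as a list with 0 members past the threshold (6.05e-05, 0.495 with an estimated correlation). After quantile normalization that list pointed the other way at 0.586.

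For vincristine 1 mg/kg at 6 h 373 genes passed, 231 up and 142 down, or 204 and 225 after quantile normalization. The count was 1392 without the 10 arrays and 230 with only the compared groups fitted. Leaving out single arrays gave 248, 173 and 229 without vehicle replicates 1, 3 and 6. The number was 718, 27, 62 and 118 without vincristine replicates 3, 4, 5 and 6.

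Colchicine 0.2 mg/kg against vehicle at 6 h asks for the early low-dose response to a compound of another chemical class. Rfx2, a transcription factor of the ciliary program (1391184_at), rose from 59.3 ± 9.46 to 402 ± 260 (log2 2.05 ± 0.3, adjusted p = 1.5e-05, n = 6 against 6, 6 of 6 animals). Fam216b, a little-studied gene, rose from 78.4 ± 16 to 301 ± 156 (log2 1.55 ± 0.31, adjusted p = 0.00536, 5 of 6). Tppp3, a protein that bundles microtubules (1398365_at), rose from 418 ± 35 to 1800 ± 1030 (log2 1.74 ± 0.41, adjusted p = 0.038, 6 of 6). Of the 9 tubulins 0 passed over all genes and 6 fell over the list alone (median log2 -0.84, camera adjusted p = 1.93e-09, 0.0362 with an estimated correlation). When the 10 arrays were left out, 2 of them in this group, 6 tubulins fell over all genes, and the means were 757 for Tuba4a and 693 for Tubb4b against 5340 and 3310 in vehicle, where all 6 colchicine arrays gave 2410 and 1590.

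Only 4 of the 6 colchicine 0.2 mg/kg animals at 6 h showed a large rise: Rfx2 spread from 62.7 to 652 within the group. Tppp3 stood at log2 11.18 to 11.38 in replicates 2 to 5 but at 8.82 and 9.09 in replicates 1 and 6, against 8.56 to 8.91 in vehicle. Without these 2 arrays the means were 567 for Rfx2 and 2460 for Tppp3, and the log2 changes were 2.96, 2.52 and 2.14 for Rfx2, Tppp3 and Fam216b. The Rfx2 call was lost when only the compared groups were fitted (0.128), as was that of Fam216b (0.0955). The call of Tppp3 was lost in that fit (0.128) and without the 6 arrays ending in _2 (0.0551). It was also lost without vehicle replicates 1 (0.0674), 3 (0.0679), 5 (0.054) or 6 (0.0857), or without colchicine replicates 2 (0.121), 3 (0.145), 4 (0.155) or 5 (0.133).

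In total 31 genes passed for colchicine 0.2 mg/kg at 6 h, 28 up and 3 down, or 36 and 9 after quantile normalization, with 756 under an unadjusted p of 0.05. It was 166 without the 10 arrays, with the mean of probe sets 48, with array weights 146 and with only the compared groups fitted 4. The number was 11, 15, 19 and 14 without vehicle replicates 1, 3, 5 and 6. Without colchicine replicates 1 to 6 in turn it was 80, 10, 11, 9, 12 and 59.

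**Figure D3:**
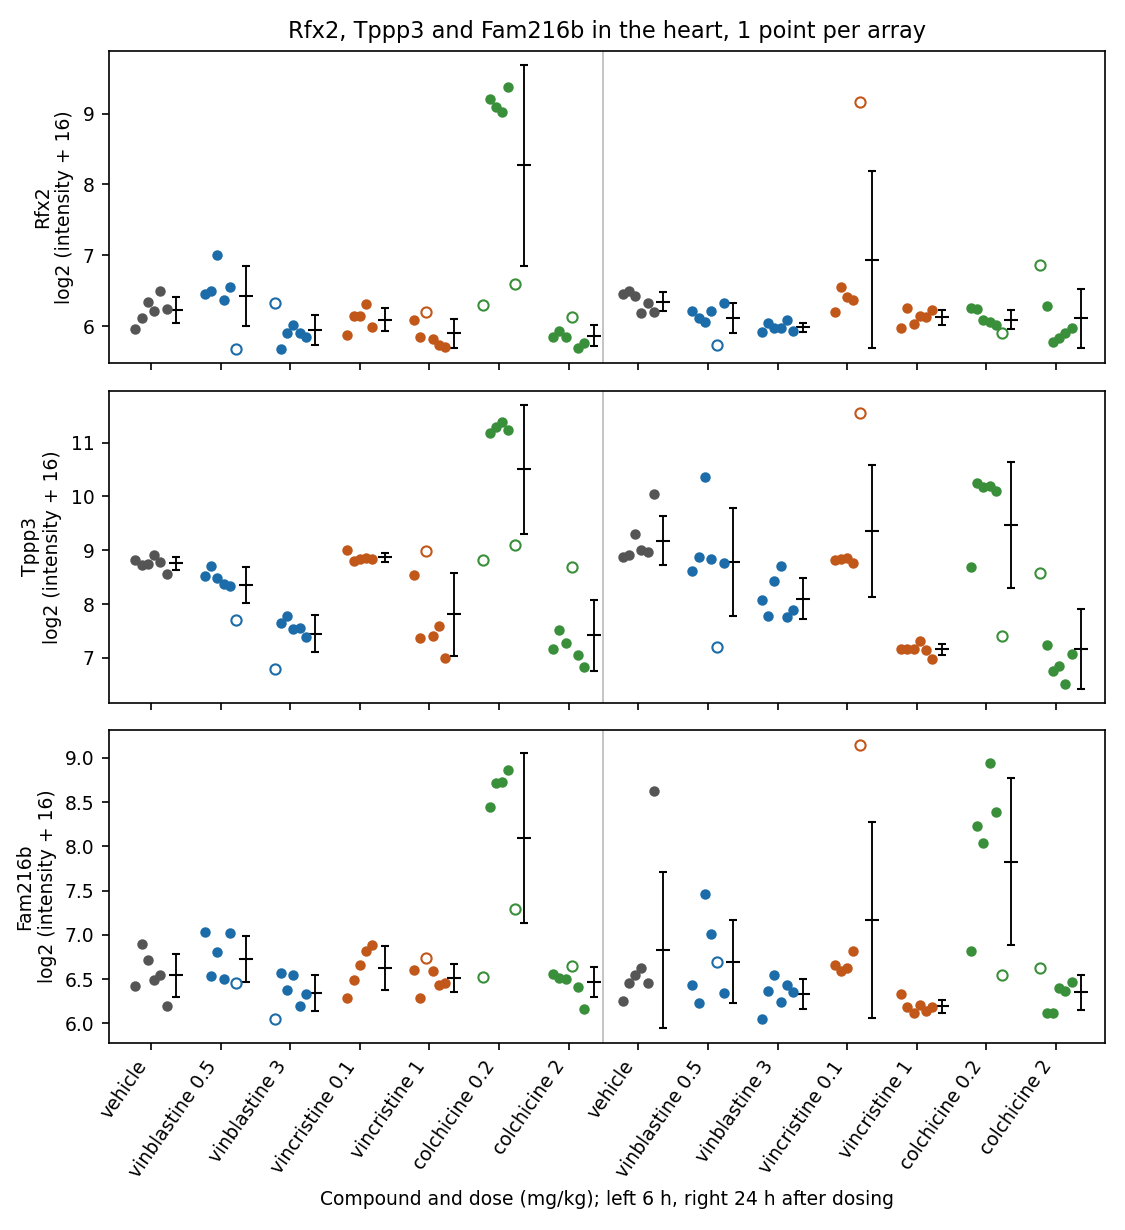
Each point is the log2 intensity of Rfx2, Tppp3 or Fam216b on 1 array, with group mean and standard deviation in black and the 10 arrays as open points. The array labelled vincristine 0.1 mg/kg at 24 h replicate 5 stood at log2 9.16, 11.56 and 9.15, at least as high as colchicine 0.2 mg/kg replicate 4 at 6 h (9.03, 11.38 and 8.73), while colchicine replicates 1 and 6 stood lower (Rfx2 6.3 and 6.6).

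Colchicine 2 mg/kg against vehicle at 6 h asks for its early high-dose response. Ccn1, a matrix protein induced by YAP and SRF, rose from 50.3 ± 17 to 679 ± 382 (log2 3.12 ± 0.71, adjusted p = 0.00178, n = 6 against 6, 6 of 6 animals). Tinagl1, a matrix glycoprotein, rose from 261 ± 45.3 to 1270 ± 480 (log2 2.06 ± 0.32, adjusted p = 4.53e-05, 6 of 6). S100a9 reached 693 ± 326 (log2 2.88 ± 0.53, adjusted p = 0.000202, 5 of 6). Tuba4a fell to 1300 ± 1670 (log2 -2.61 ± 0.49, adjusted p = 0.000228, 6 of 6) and Tubb4b to 950 ± 1130 (-2.28 ± 0.42, 0.000202, 6 of 6). In replicate 4 they stood at 4690 and 3240. Without it the means were 627 and 492, and the change of S100a9 was log2 3.55.

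Endothelial genes moved in both directions 6 h after colchicine 2 mg/kg. Sox18, an endothelial transcription factor, fell from 890 ± 79.3 to 421 ± 211 (log2 -1.15 ± 0.2, adjusted p = 0.000114, 6 of 6), and Emcn, an endothelial surface mucin, fell by 0.65 ± 0.12 (0.000171, 6 of 6). Icam1 rose by log2 1.26 ± 0.24 (adjusted p = 0.000253, 6 of 6). Of 14 activation and coagulation genes 9 rose and 1 fell, 10 and 1 over the list alone (median log2 0.78, camera adjusted p = 1.35e-07, 0.112 with an estimated correlation). Of 26 endothelial markers 4 rose and 6 fell, 6 and 8 over the list alone (0.179).

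Cardiac stress genes rose in 7 of 14, 10 over the list alone (1.28e-07, 0.123 with an estimated correlation) after colchicine 2 mg/kg at 6 h, and immediate early genes in 9 of 22, 12 over the list alone (1.87e-06 and 0.243). NF-kappaB and acute phase genes rose in 7 of 16, 9 over the list alone (3.06e-07 and 0.123). Glucocorticoid response genes rose in 4 of 12, 8 over the list alone (1.74e-05 and 0.121), with the metallothionein Mt2A at log2 2.06 ± 0.46 (adjusted p = 0.00174, 6 of 6). Ndrg1 rose from 355 ± 38.4 to 740 ± 162 (log2 1 ± 0.13, adjusted p = 1.12e-06, 6 of 6). Gja1, the main gap junction protein of the ventricle, fell by 0.62 ± 0.15 (adjusted p = 0.00376, 5 of 6). The comparison gave 1050 genes, 553 up and 497 down, with 2185 without the 10 arrays, 1620 without colchicine replicate 4 and 2389 with array weights.

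**Figure D4:**
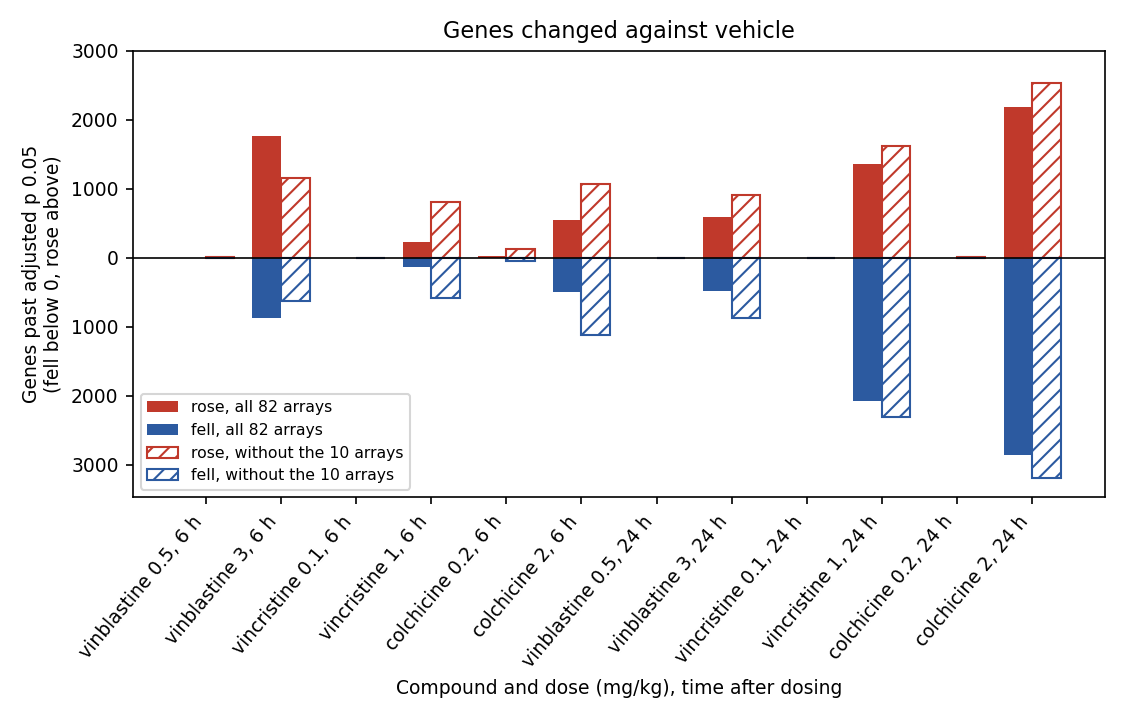
Bars give the number of genes that rose (upward) or fell (downward) past an adjusted p of 0.05 in each vehicle comparison, filled for all 82 arrays and hatched without the 10 arrays. Colchicine 2 mg/kg at 24 h had the most, with 2178 up and 2866 down.

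At 24 h the low doses gave 0 genes each in limma: vinblastine 0.5 mg/kg with 227 under an unadjusted p of 0.05, vincristine 0.1 mg/kg with 316 and colchicine 0.2 mg/kg with 290. Array weights gave 3, 53 and 4, and leaving out the 10 arrays gave 1, 0 and 3. Mean Tuba4a was 4060 ± 1940 (n = 6), 4680 ± 2260 (n = 5) and 2960 ± 1550 (n = 6) in these groups, against 5580 ± 1400 in vehicle. Each of the 3 groups holds 1 of the 10 arrays, with Tuba4a at 709, 760 and 671. Without these the means were 4730, 5660 and 3410, so that of vincristine was not below vehicle. Mitosis genes moved down as a list with vinblastine (camera adjusted p = 1.25e-09, 0.166 with an estimated correlation) and colchicine (1.11e-05 and 0.397). Tubulins moved down with colchicine (median log2 -0.53, 1.61e-05 and 0.22). For vincristine the glucocorticoid response list moved up (0.00212 and 0.96). In none of these lists did a member pass over all genes.

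Vinblastine 3 mg/kg against vehicle at 24 h asks what remains or appears a day after a high dose. Sult1a1, a sulfotransferase of xenobiotic metabolism, rose from 284 ± 113 to 1270 ± 366 (log2 2.13 ± 0.22, adjusted p = 6.99e-11, n = 6 against 6, 6 of 6 animals). Myh7, the slow myosin heavy chain that returns in strained rat ventricle, rose from 3590 ± 575 to 14400 ± 2520 (log2 1.99 ± 0.31, adjusted p = 4.37e-06, 6 of 6). Mx1, an interferon-induced antiviral GTPase, rose from 36.5 ± 3.19 to 271 ± 202 (log2 2.12 ± 0.34, adjusted p = 5.66e-06, 6 of 6). Tfrc, the transferrin receptor for iron uptake, fell from 2890 ± 660 to 457 ± 180 (log2 -2.66 ± 0.34, adjusted p = 3.9e-08, 6 of 6). Lyve1, a receptor of lymphatic endothelium and resident macrophages, rose from 252 ± 40.8 to 753 ± 125 (log2 1.52 ± 0.18, adjusted p = 4.37e-09, 6 of 6).

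Interferon response genes rose in 14 of 19 with 0 falling 24 h after vinblastine 3 mg/kg, 17 over the list alone, and the call held with an estimated correlation (median log2 0.9, camera adjusted p = 3.69e-23, then 0.0225). Isg15, a ubiquitin-like interferon product, rose from 273 ± 47.1 to 1290 ± 870 (log2 1.89 ± 0.29, adjusted p = 2.1e-06, 6 of 6). Glucocorticoid response genes rose in 4 of 12, 7 over the list alone, and held as well (median log2 0.73, 3.88e-08, then 0.0257), led by Fkbp5, a receptor co-chaperone, at 1.96 ± 0.34 (adjusted p = 2.73e-05, 6 of 6). Monocyte and macrophage markers rose in 9 of 17, 11 over the list alone (1.26e-09, 0.0576 with an estimated correlation), and 10 of 22 unfolded protein response genes rose and 1 fell, 13 and 1 over the list alone (1.47e-06 and 0.219).

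Mitosis genes fell in 8 of 22, 10 over the list alone (median log2 -0.2, 5.8e-06, 0.276 with an estimated correlation), among them Racgap1, needed for cytokinesis (log2 -0.53 ± 0.11, adjusted p = 0.000828, 6 of 6) at 24 h after vinblastine. Tubulins no longer shifted as a list (adjusted p = 0.693): 3 rose and 1 fell, the same over the list alone, with a median of 0.08 and a mean of -0.04. Erythroid markers fell in 3 of 6 (0.00307 and 0.232), with Slc4a1, the red cell anion exchanger, at log2 -1 ± 0.23 (adjusted p = 0.00143, 6 of 6). Altogether 1082 genes passed, 597 up and 485 down, with 1782 without the 10 arrays and 2403 with array weights.

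Vincristine 1 mg/kg against vehicle at 24 h asks the same of the second vinca compound. Angptl4, a lipoprotein lipase inhibitor, rose from 40.1 ± 4.13 to 671 ± 318 (log2 3.46 ± 0.44, adjusted p = 1.18e-08, n = 6 against 6). Hamp, the iron hormone hepcidin, rose from 86.3 ± 26.3 to 810 ± 201 (log2 3.01 ± 0.54, adjusted p = 9.65e-06), and Ankrd23 from 164 ± 43 to 1500 ± 558 (log2 3.02 ± 0.44, adjusted p = 1.6e-07). Tfrc fell from 2890 ± 660 to 198 ± 61.5 (log2 -3.76 ± 0.34, adjusted p = 1.59e-13). Tuba4a was still low at 930 ± 164 against 5580 ± 1400 (log2 -2.53 ± 0.49, adjusted p = 3.69e-05). Each of these held in 6 of 6 animals.

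Myh7 rose from 3590 ± 575 to 15500 ± 1990 with vincristine 1 mg/kg at 24 h (log2 2.11 ± 0.31, adjusted p = 2.33e-07) and Nppa, the atrial natriuretic peptide gene, from 1820 ± 768 to 7110 ± 2700 (log2 1.98 ± 0.41, adjusted p = 9.73e-05), each in 6 of 6 animals. Cardiac stress genes rose in 10 of 14, the same over the list alone (median log2 0.92, camera adjusted p = 1.02e-07, 0.256 with an estimated correlation). Of 20 ion channel and calcium handling genes 10 fell and 1 rose, the same over the list alone (0.00427 and 0.307). Kcnd2, a channel of the transient outward current, fell from 154 ± 30.6 to 70.5 ± 11.5 (log2 -0.96 ± 0.15, adjusted p = 3.11e-07), and Slc8a1, the sodium-calcium exchanger, fell by 0.71 ± 0.11 (1.6e-06), each in 6 of 6 animals. Oxidative phosphorylation genes fell in 18 of 35, 21 over the list alone (median log2 -0.16, 1.2e-06, 0.474 with an estimated correlation). Ndufb10, a subunit of complex I, fell from 4010 ± 402 to 2500 ± 180 (log2 -0.68 ± 0.1, adjusted p = 3.52e-07, 6 of 6).

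Interferon genes rose in 17 of 19, also 17 over the list alone (median log2 0.91, 1.32e-13, 0.256 with an estimated correlation), with Ifit3 at log2 2.17 ± 0.31 (adjusted p = 8.34e-08, 6 of 6), 24 h after vincristine 1 mg/kg. Monocyte and macrophage markers rose in 9 of 17, 11 over the list alone (1.2e-06 and 0.256), with the endotoxin co-receptor Cd14 at 1.74 ± 0.24 (3.95e-08, 6 of 6). Oxidative stress genes rose in 7 of 12, 8 over the list alone (9.34e-05 and 0.305), with heme oxygenase Hmox1 at 1.49 ± 0.29 (3.69e-05, 6 of 6). Heat shock genes fell in 8 of 14 with 2 rising, the same over the list alone (0.00411 and 0.307). In total 3433 genes passed, 1353 up and 2080 down, or 1842 and 1834 after quantile normalization, and 3943 without the 10 arrays.

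Colchicine 2 mg/kg against vehicle at 24 h gave the most genes past the threshold of all comparisons. Hamp rose from 86.3 ± 26.3 to 3010 ± 1900 (log2 4.28 ± 0.54, adjusted p = 1.03e-09, n = 6 against 6, 6 of 6 animals). Lcn2, an iron-binding acute phase protein, rose from 195 ± 45.5 to 3810 ± 2250 (log2 3.71 ± 0.41, adjusted p = 5.7e-11, 6 of 6). Ankrd23 rose by 4.04 ± 0.44 (3.11e-11, 6 of 6) and Cdo1, which breaks down cysteine, from 96.5 ± 9.13 to 1880 ± 962 (log2 3.63 ± 0.41, adjusted p = 1.1e-10, 6 of 6). Perm1, a muscle regulator of mitochondrial genes, fell from 2770 ± 286 to 597 ± 763 (log2 -2.79 ± 0.31, adjusted p = 4.09e-11, 6 of 6). Rab3a, a vesicle GTPase, fell from 546 ± 45 to 125 ± 142 (log2 -2.37 ± 0.22, adjusted p = 5.25e-13, 6 of 6). On colchicine replicate 1, 1 of the 10 arrays, Hamp stood at log2 6.93, within the vehicle range of 6.4 to 7.26, and on the other 5 at 11.06 to 12.32. Without that array the changes were 5.08 for Hamp, 4.38 for Lcn2, 4.66 for Ankrd23 and 4.3 for Cdo1. Tuba4a stood at 620 ± 80.8 against 5580 ± 1400 (log2 -3.09 ± 0.49, adjusted p = 2.49e-07, 6 of 6), and 5 of 9 tubulins fell, the same 5 over the list alone, without a list call (median log2 -0.68, 0.0718).

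Oxidative phosphorylation fell in 28 of 35 genes, 29 over the list alone (median log2 -0.21, camera adjusted p = 3.13e-07, 0.485 with an estimated correlation), 24 h after colchicine 2 mg/kg. Sdhd, an anchor subunit of complex II, fell from 7470 ± 294 to 4890 ± 1290 (log2 -0.64 ± 0.09, adjusted p = 6.74e-09, 6 of 6). Fatty acid oxidation genes fell in 13 of 25 and rose in 3, 14 and 3 over the list alone (0.0312 and 0.588, 0.0959 with the stricter filter and 0.0579 with the mean of probe sets). Ion channel and calcium handling genes fell in 12 of 20 with 1 rising, the same over the list alone (0.00449 and 0.334), Slc8a1 from 2160 ± 282 to 1140 ± 478 (log2 -0.99 ± 0.11, adjusted p = 1.62e-10, 6 of 6). Cardiac stress genes rose in 12 of 14, the same over the list alone (median log2 1.17, 1.45e-07 and 0.267).

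Unfolded protein response genes rose in 16 of 22 with 1 falling (median log2 0.56, camera adjusted p = 1.45e-07, 0.267 with an estimated correlation), and ribosome biogenesis genes in 16 of 18 with 0 falling (1.56e-07 and 0.334), the same numbers over each list alone, 24 h after colchicine 2 mg/kg. Myc, a driver of ribosome production, rose by log2 2.62 ± 0.36 (adjusted p = 1.24e-08, 6 of 6), and the nucleolar protein Gnl3 by 1.1 ± 0.16 (1.92e-08, 6 of 6). Hmox1 rose from 158 ± 29.9 to 990 ± 444 (log2 2.32 ± 0.29, adjusted p = 7.88e-10, 6 of 6). Of 23 fibroblast and matrix genes 15 fell and 5 rose, 16 and 5 over the list alone (0.0143 and 0.523), with the basement membrane collagen Col15a1 falling from 4430 ± 446 to 1430 ± 990 (log2 -1.8 ± 0.18, adjusted p = 6.41e-12, 6 of 6). NF-kappaB and acute phase genes rose in 13 of 16, the same over the list alone (1.26e-06 and 0.267). Glycolysis genes had a median of -0.07, a mean of 0.15 and no call (0.47), and smooth muscle and pericyte markers a median of 0.05, a mean of -0.2 and no call (0.491). The total was 5044 genes, 2178 up and 2866 down, with 5717 without the 10 arrays.

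**Figure D5:**
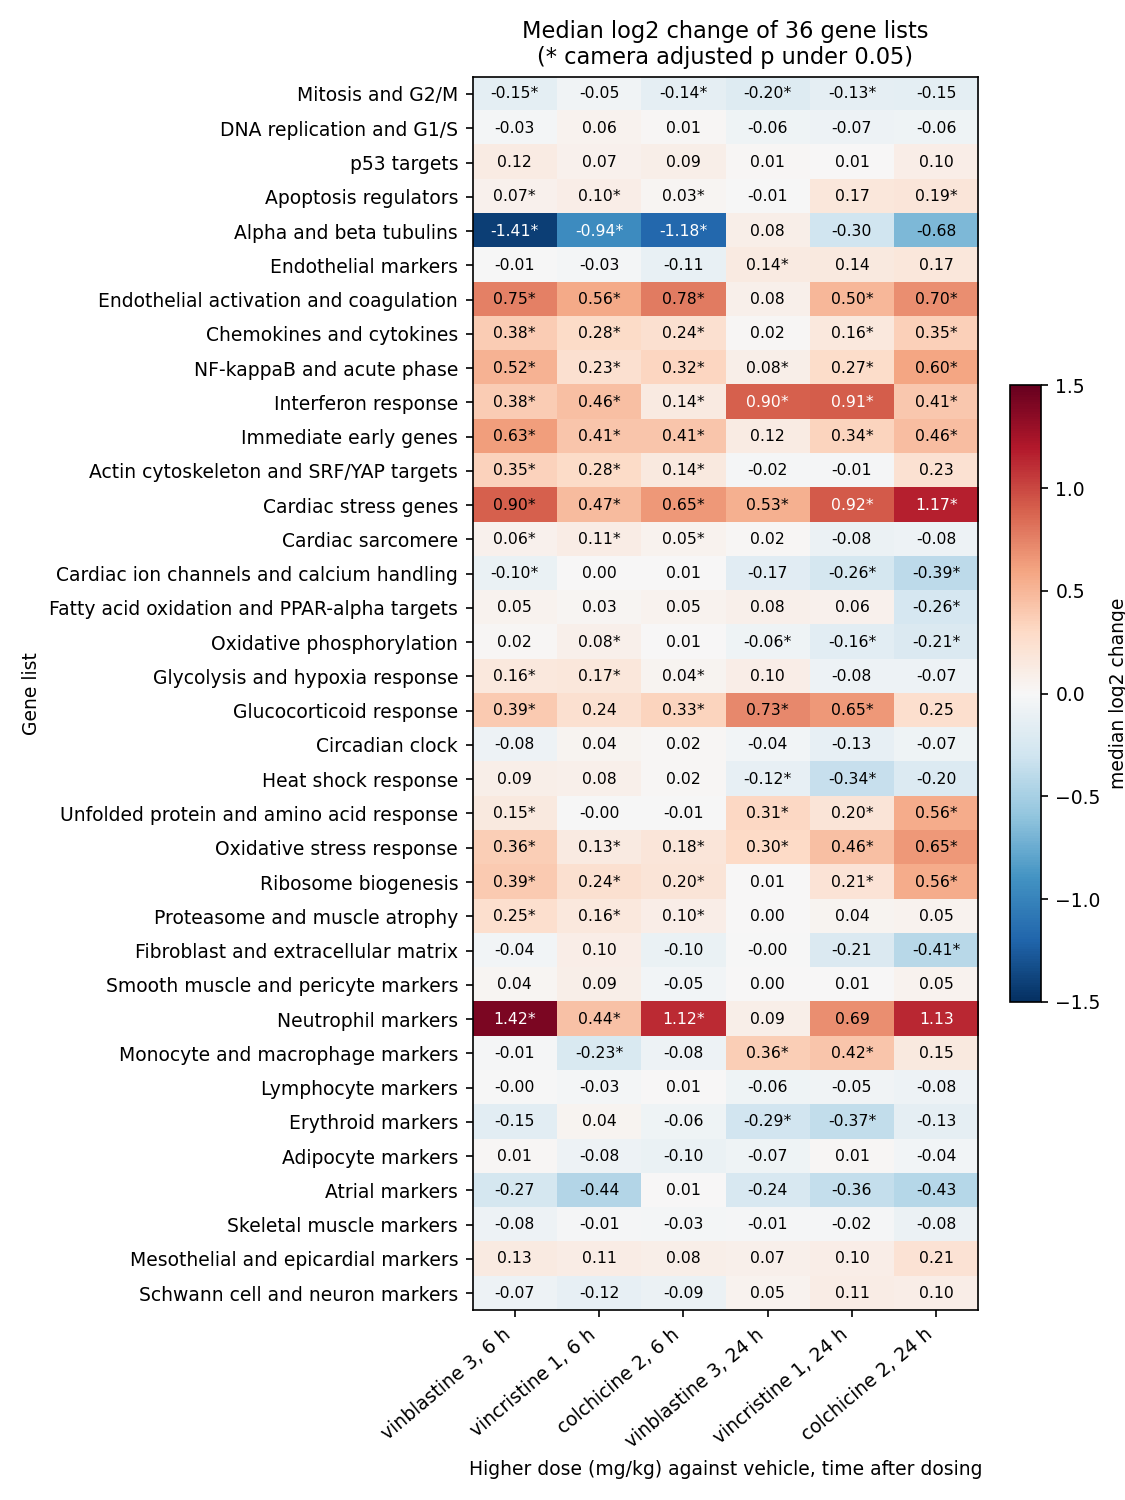
Cells give the median log2 change of each of 36 gene lists for the higher doses against vehicle, with a star where the camera adjusted p was under 0.05 at the preset correlation. Tubulins had medians of -1.41, -0.94 and -1.18 at 6 h for vinblastine, vincristine and colchicine, and 0.08, -0.3 and -0.68 at 24 h.

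Among all list calls, 8 held when the correlation between genes was estimated. Against vehicle these were tubulins with vinblastine 0.5 mg/kg (0.00011) and colchicine 0.2 mg/kg (0.0362) at 6 h, and the interferon (0.0225) and glucocorticoid (0.0257) responses with vinblastine 3 mg/kg at 24 h. Elsewhere they were the actin and SRF/YAP targets by vincristine dose at 6 h (0.0249), the interferon response by vinblastine dose at 24 h (0.0193), tubulins between the lower doses of the vinca compounds at 6 h (0.0125), and monocyte and macrophage markers over time with vincristine (0.0326).

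The higher dose of each compound was set against its lower dose to ask which changes depend on dose at 6 h. For vinblastine S100a9 was higher by log2 2.39 ± 0.53 (adjusted p = 0.00389) and Tnfrsf12a by 2.35 ± 0.47 (0.00229), each on 6 against 6 animals. S100a9 was higher by 3.01 without the 10 arrays, here lower-dose replicate 6 and higher-dose replicate 1. For vincristine Tnfrsf12a was higher by 2.19 ± 0.49 (adjusted p = 0.00884, 6 of 6 animals against 5) and Tuba4a lower (-2.09 ± 0.51, 0.0153, 5 of 6). The Tuba4a call was lost without higher-dose replicates 2 (0.0585), 4 (0.061) or 6 (0.0563), and when only the compared groups were fitted (0.056). For colchicine Adamts1 was higher by 2.43 ± 0.46 (0.000209, 5 of 6), and Tppp3 fell from 1800 ± 1030 to 174 ± 112 (log2 -3.08 ± 0.41, adjusted p = 2.78e-07, 6 of 6), or log2 -4.11 without the 10 arrays, 3 of them in these groups. Zfp423, a zinc finger transcription factor, fell from 496 ± 160 to 129 ± 49.4 (log2 -1.81 ± 0.24, adjusted p = 3.27e-07, 6 of 6). Cardiac stress genes were higher with dose for vinblastine in 8 of 14, 12 over the list alone (2.99e-10, 0.11 with an estimated correlation). Immediate early genes were higher for colchicine in 12 of 22, 14 over the list alone (1.95e-11 and 0.0685). Actin and SRF/YAP targets were higher for vincristine in 5 of 20, 13 over the list alone (2.08e-10, then 0.0249).

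The dose comparisons at 6 h gave 955 genes for vinblastine (650 up, 305 down), 317 for vincristine (181 and 136) and 1042 for colchicine (503 and 539). After quantile normalization the splits were 647 and 556 for vinblastine and 188 and 216 for vincristine. Without the 10 arrays there were 1094, 1273 and 1715. For vinblastine the S100a9 and Tnfrsf12a calls ended when only the compared groups were fitted (0.103 and 0.101), where 0 genes passed, and 33 passed without the 6 arrays ending in _2. That count was 459, 573, 572 and 1533 without lower-dose replicates 1, 3, 5 and 6, and 189 without higher-dose replicate 1. For vincristine it was 111, 111 and 179 without lower-dose replicates 2, 3 and 5, and 135, 655, 78, 133 and 131 without higher-dose replicates 2 to 6, with 142 without the 6 arrays ending in _2 and 650 with array weights. For colchicine it was 684 and 1600 without higher-dose replicates 2 and 4, and 2621 with array weights.

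At 24 h the dose comparisons repeated the leading genes of the higher doses. Between 0.5 and 3 mg/kg vinblastine Sult1a1 was higher by log2 2.08 ± 0.22 (adjusted p = 1.84e-10), and Penk, the enkephalin precursor, rose from 1330 ± 520 to 5010 ± 1340 (log2 1.99 ± 0.33, adjusted p = 2.11e-05, n = 6 against 6). Tfrc was lower with dose for vinblastine (-2.56 ± 0.34, 1.86e-07), vincristine (-3.79 ± 0.36, 8.96e-13) and colchicine (-2.71 ± 0.34, 1.68e-09, 5 of 6 animals). Angptl4 was higher by 3.5 ± 0.47 for vincristine (4.64e-08) and Hamp by 4.01 ± 0.54 for colchicine (7.94e-09). For colchicine the changes without the 10 arrays, here 0.2 mg/kg replicate 6 and 2 mg/kg replicate 1, were 5.17 for Hamp and -3.45 for Tfrc. Interferon genes were higher with vinblastine dose in 15 of 19, the same over the list alone (9.22e-24, then 0.0193 with an estimated correlation). Oxidative phosphorylation genes were lower with colchicine dose in 29 of 35, 31 over the list alone (8.83e-09 and 0.437). The counts were 620 for vinblastine (443 up, 177 down), 2702 for vincristine (1388 and 1314) and 4686 for colchicine (2123 and 2563). Without the 10 arrays they were 1251, 3085 and 5537, and array weights gave 1430 and 4579 for the vinca compounds.

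Vinblastine and vincristine differ in an N-methyl against an N-formyl group, while colchicine binds another site on tubulin, so the higher doses were set against each other to ask whether the hearts differ. The doses differ between compounds, so a difference need not belong to the compound. At 6 h limma found 0 genes for vinblastine against vincristine (1511 under an unadjusted p of 0.05), 0 for vinblastine against colchicine (1192) and 0 for vincristine against colchicine (677). Tuba4a differed by log2 -0.9 (95% interval -1.87 to 0.08), -0.38 (-1.35 to 0.6) and 0.52 (-0.45 to 1.49) in that order. S100a9 differed by 1.57 (0.51 to 2.63, adjusted p = 0.2) between the vinca compounds. The interval lay within ±1 for 11173, 11240 and 11235 of 11319 genes. At 24 h, where every pair had genes past the threshold, it did so for 11116, 10681 and 11062. These numbers therefore do not show that the hearts were alike at 6 h. Vincristine against colchicine gave 82 genes without the 10 arrays, 35 without colchicine replicate 4 and 190 with array weights. Vinblastine gave 3 genes against vincristine without vincristine replicate 5, 5 against colchicine without the 10 arrays and 28 against colchicine with array weights.

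At 24 h the vinca compounds differed in 532 genes, 411 higher and 121 lower with vinblastine. Angptl4 was lower with vinblastine (113 ± 25.3 against 671 ± 318, log2 -2.28 ± 0.44, adjusted p = 0.00125, n = 6 against 6). Hey1, a Notch target, was higher (355 ± 56.7 against 139 ± 28.2, log2 1.26 ± 0.25, adjusted p = 0.00157). Tuba8 was higher by 1.5 ± 0.41 (adjusted p = 0.0213), a call lost without vinblastine replicates 1 (0.052) or 4 (0.0672) or vincristine replicate 5 (0.055). Chemokines were lower with vinblastine in 4 of 17, 5 over the list alone (2.26e-05, 0.295 with an estimated correlation). The split after quantile normalization was 351 and 299. Counts were 1509 without the 10 arrays, 825 without the 6 arrays ending in _2, 890 with only the compared groups and 1503 with array weights. Single arrays gave 293, 278 and 844 without vinblastine replicates 1, 4 and 5, and 249 without vincristine replicate 5.

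Vinblastine and colchicine differed in 3866 genes at 24 h, 2309 higher and 1557 lower with vinblastine. Cdo1 stood at 145 ± 26.1 against 1880 ± 962 (log2 -3.12 ± 0.41, adjusted p = 2.95e-08, n = 6 against 6, or log2 -3.79 without colchicine replicate 1), and Fbxl22, an F-box protein of the cardiac Z-disc, was higher by 2.39 ± 0.27 (1.54e-09). Ribosome biogenesis genes were lower with vinblastine in 15 of 18, 16 over the list alone (4.47e-11, 0.367 with an estimated correlation), and oxidative phosphorylation genes higher in 21 of 35, 23 over the list alone (6.56e-06 and 0.45). There were 4923 genes without the 10 arrays and 2057 with only the compared groups.

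Vincristine and colchicine differed in 1117 genes at 24 h, 569 higher and 548 lower with vincristine. Tnfsf10, the death ligand TRAIL induced by interferon, stood at 165 ± 55.9 against 47.8 ± 23.6 (log2 1.51 ± 0.23, adjusted p = 7.14e-06, n = 6 against 6), and Sult1a1 was higher by 1.41 ± 0.22 (1.33e-05). Cdo1 was lower by 2 ± 0.41 (0.000916), a call lost when only the compared groups were fitted (0.115). Without the 10 arrays, of which colchicine replicate 1 is in this comparison, it was log2 -2.67. Those arrays were set apart by these same profiles, so that fit does not restore the call. Fatty acid oxidation genes were higher with vincristine in 13 of 25, 18 over the list alone (2.13e-12, 0.175 with an estimated correlation), and unfolded protein genes lower in 11 of 22, 14 over the list alone (1.76e-08 and 0.175). Counts were 2942 without the 10 arrays, 2706 with array weights and 46 with only the compared groups. Without colchicine replicates 1, 3, 4 and 5 there were 2409, 322, 739 and 709.

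At the lower doses the vinca compounds differed in 7 genes at 6 h, with 880 under an unadjusted p of 0.05. Tuba4a stood at 720 ± 87.8 with vinblastine (n = 6) and 5360 ± 411 with vincristine (n = 5), log2 -2.87 ± 0.51 (adjusted p = 0.00383), and Tubb4b was lower by 2.35 ± 0.44 (0.00561). The tubulin list fell in 2 of 9, 5 over the list alone (median log2 -1.15, 2.35e-11, then 0.0125 with an estimated correlation). There were 17 genes without the 10 arrays, with array weights 23, with only the compared groups 12 and without the 6 arrays ending in _2 there were 4. At 24 h limma found 0 genes, with 279 under an unadjusted p of 0.05 and 4 with array weights. Tuba4a then differed by -0.17 (95% interval -1.19 to 0.85).

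The changes against vehicle ran in parallel across compounds. At 6 h the correlation over 11319 genes was 0.87 for vinblastine and vincristine, 0.9 for vinblastine and colchicine and 0.87 for vincristine and colchicine. At 24 h it was 0.83, 0.67 and 0.89. Genes are not independent replicates, and shared vehicle animals alone gave 0.5 in simulation. With separate sets of 3 vehicle animals the means over 20 splits were 0.71, 0.77 and 0.69 at 6 h and 0.76, 0.61 and 0.85 at 24 h. The covariance was 0.0525, 0.0666 and 0.0432 at 6 h and 0.0673, 0.0714 and 0.141 at 24 h, against about 0.0061 in simulation.

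Many calls were shared between compounds. At 24 h vincristine and colchicine had 1082 genes up in both, where independent lists would share 260, and 1814 down in both (527), with 3 in opposite directions. Vinblastine shared 396 up (115) and 400 down (123) with colchicine, with 23 opposite, and 467 up (71.4) and 422 down (89.1) with vincristine, with 0 opposite. At 6 h vinblastine shared 223 up (36.1) and 126 down (10.9) with vincristine, and 521 up (86.4) and 384 down (38.1) with colchicine. Vincristine and colchicine shared 185 up (11.3) and 117 down (6.24), and 0 genes were opposite in any pair at 6 h. With separate sets of 3 vehicle animals the mean shared rises and falls at 24 h for vincristine and colchicine were 637.9 and 1164.8. At 6 h they were 28.6 and 7.7 for vinblastine and vincristine, 216.7 and 110.9 for vinblastine and colchicine, and 12.7 and 5.2 for vincristine and colchicine. For vinblastine at 24 h they were 219.4 and 133.9 with vincristine and 176.8 and 132.4 with colchicine. The simulation gave 0 shared calls.

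Time was examined by setting the change at 24 h against the change at 6 h within a compound, to ask which responses fade or grow. For vinblastine the change of Tubb2a, a beta tubulin, was higher at 24 h by log2 2.62 ± 0.49 (adjusted p = 0.00106) and that of Tubb4b by 2.35 ± 0.59 (0.0132). At 24 h Tubb2a stood at 2030 ± 335 against 962 ± 201 in vehicle, and Tubb4b at 2860 ± 373 against 3280 ± 761. Tubulins rose between the times in 4 of 9 and fell in 1, 8 and 1 over the list alone (7.05e-07, 0.107 with an estimated correlation). For vincristine Tfrc was lower by 4.07 ± 0.48 (2.1e-08), and Mgst1, a microsomal glutathione transferase, higher by 2.16 ± 0.37 (9.63e-05). Monocyte and macrophage markers rose over time in 10 of 17, 13 over the list alone (2.43e-13, then 0.0326), and oxidative phosphorylation genes fell in 18 of 35, 29 over the list alone (2.43e-13 and 0.361). List tests other than those against vehicle were not rerun after quantile normalization. Under it the upward shift of oxidative phosphorylation with vincristine at 6 h, part of this comparison, pointed the other way (camera adjusted p = 0.586). For colchicine Hamp was higher by 3.16 ± 0.76 (0.0017) and Fbxl22 lower (-2.25 ± 0.39, 3.48e-05). Each rests on 4 groups of 6 animals.

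The time comparisons gave 497 genes for vinblastine (201 up, 296 down), 1385 for vincristine (399 and 986) and 2136 for colchicine (712 and 1424). After quantile normalization the splits were 372 and 226, 676 and 574, and 1131 and 1261. Without the 10 arrays the counts were 918, 1788 and 3188, and with array weights 1278, 2155 and 3546. For vinblastine it was 318 and 330 without 6 h vehicle replicates 3 and 6, and 325 without 24 h vehicle replicate 3.

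Vehicle hearts at 24 h against 6 h, which asks what time alone does, differed in 1 gene, with 1426 under an unadjusted p of 0.05. Per3, a gene of the circadian clock, fell from 201 ± 85.1 to 77.5 ± 12.9 (log2 -1.14 ± 0.22, adjusted p = 0.0237, n = 6 against 6, 6 of 6). Its call was lost with the mean of probe sets (0.0632), without the 6 arrays ending in _2 (0.0815) and with only the compared groups (0.0649). The same happened without 6 h replicates 1 (0.0728) or 2 (0.129) and without 24 h replicates 1 (0.104), 3 (0.0923) or 5 (0.101). Clock genes moved down as a list, with 1 of 15 falling, or 3 up and 5 down over the list alone (median log2 -0.17, 0.000592, 0.0516 with an estimated correlation). The count was 0, 0, 3, 3 and 9 without 6 h replicates 1 to 5, and 0, 2, 0, 0 and 3 without 24 h replicates 1, 2, 3, 5 and 6. It was 9 without the 10 arrays and 128 with array weights.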

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

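The tests on the arrays nearer to another group were chosen after their distances had been seen, so their bounds were written with the distances known. The tests on RNA integrity, airway genes, cilia genes and tubulin folding genes had bounds written before their values were seen. The bound of the quantile normalization test was written after its value was seen, as was the rule that a list whose brightest gene lies below the median array intensity decides nothing. The rule that the interval of the integrity correlation must exclude 0.5 was added after its value was seen. Outliers were sought with a Dixon test in 112 combinations of group and measure, of which 26 held an outlier, and chance alone marks about 1 in 20.

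The first pattern is that 10 arrays lay nearer to another group than to their own by a ratio over 1.3, by 0.288 against 0.153 for the array labelled vinblastine 0.5 mg/kg at 6 h replicate 6 and by 0.505 against 0.157 for colchicine 2 mg/kg at 24 h replicate 1. Mislabelled or exchanged arrays could produce it: 9 of the 10 arrays were no farther from the other group's median than that group's own arrays, the exception being vinblastine 3 mg/kg at 6 h replicate 1 at 0.342 against 0.261, but so were 52 of the other 72, so this test sets the 10 little apart. For a missed or ineffective dose 5 of the 10 arrays lay within the spread of vehicle, a value on its bound, and 1 of these, colchicine 2 mg/kg at 24 h replicate 1, had Tuba4a at log2 9.63 and Tubb4b at 9.53 against at least 11.54 and 10.89 in vehicle, while array quality was out of range on 1, whose Gapdh 3' to 5' ratio of 0.227 was the lowest of all and no sign of poor RNA, so the tables argue against either as the cause of all 10. For the 4 arrays labelled colchicine 0.2 mg/kg at 6 h replicates 1 and 6, colchicine 2 mg/kg at 6 h replicate 4 and vincristine 1 mg/kg at 6 h replicate 3, all 4 lay within the spread of vehicle and 1 had a clock gene score above every reference array of 6 h, so a missed dose and an exchanged array cannot be told apart. The colchicine 2 mg/kg array at 6 h was nearest to vinblastine 0.5 mg/kg at 24 h (0.146) and replicate 5 of the latter nearest to colchicine 2 mg/kg at 6 h (0.154), as an exchange of these 2 would give, but who received what stays open and every group here is as labelled.

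Another 35 arrays, 8 of them vehicle, lay nearer to another group than to their own by a ratio of at most 1.24.

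Colchicine 0.2 mg/kg at 24 h replicate 6 was nearest to vincristine 1 mg/kg at 6 h (0.163 against 0.309 to its own group) and vincristine 0.1 mg/kg at 24 h replicate 5 to colchicine 0.2 mg/kg at 6 h (0.163 against 0.232). A score over 15 clock genes, set on the vehicle and lower-dose arrays outside the 10, ran from -0.73 to 0.14 on 20 arrays of 6 h and from -0.62 to 1.46 on 20 of 24 h, of which 15 lay above 0.14. Among the 4 arrays it was 0 and 0.76 for colchicine 0.2 mg/kg replicates 1 and 6, -0.17 for colchicine 2 mg/kg replicate 4 and -0.01 for vincristine 1 mg/kg replicate 3. It was 1.23 for vinblastine 3 mg/kg at 6 h replicate 1 and, at 24 h, -0.38 for vinblastine 0.5 mg/kg replicate 5, -0.69 for vincristine 0.1 mg/kg replicate 5 and -0.23 for colchicine 0.2 mg/kg replicate 6.

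The second pattern is that another split of the 6 h arrays of vehicle and vincristine 0.1 mg/kg gave up to 981 genes where the real grouping gave 0. After quantile normalization the highest number over 100 splits was 128, which fits brightness-dependent differences between arrays left by the authors' normalization. Splits with over 100 genes went from 4 to 1. Differences in RNA integrity could also act, but the correlation of the brightness slope with the hexokinase 3' to 5' ratio was 0.22 over 11 arrays (95% interval -0.44 to 0.72), which decides nothing. Whether such a structure of the samples adds error to other comparisons at 6 h was not tested, and its origin stays open.

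The third pattern is the rise of Rfx2, Tppp3 and Fam216b with colchicine 0.2 mg/kg at 6 h. Airway or lung tissue in the sample would raise airway and alveolar genes, yet 0 of 10 measured rose (the brightest, Ager, log2 -0.2). A wider rise of motile cilia genes was seen in 0 of 17 measured, of 36 listed (log2 -0.07 to 0.06). The brightest, Cfap126, stood at log2 6.07, below the median array's 6.27. Rfx2 rose from a similar level (5.96 to 6.49 in 6 h vehicle). No cilia gene rose as far, and by the rule above genes so dim decide nothing more. Both lists were first run on the filtered genes (3 and 4 measured, 0 rising), then without the filter, a step chosen after that was seen. Whether the rise is an effect of the dose in heart cells was not tested and stays open.

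The array labelled vincristine 0.1 mg/kg at 24 h replicate 5 had Rfx2 at 555 and Tppp3 at 3000. At 24 h Tppp3 was also high, at log2 10.11 to 10.25, in colchicine 0.2 mg/kg replicates 2 to 5, at 10.37 in vinblastine 0.5 mg/kg replicate 3 and at 10.04 in vehicle replicate 6. Fam216b stood at 8.04 to 8.94, 7.46 and 8.62 on these arrays and Tuba4a at 11.2 to 11.78, 11.41 and 11.54, with Rfx2 between 6.02 and 6.24. Colchicine 0.2 mg/kg replicates 1 and 6 stood at 8.68 and 7.41 for Tppp3, 6.82 and 6.54 for Fam216b and 12.41 and 9.42 for Tuba4a. Vehicle replicate 6 lay nearer to colchicine 0.2 mg/kg at 24 h (0.163) than to vehicle (0.193). Colchicine 0.2 mg/kg replicate 1 lay nearer to vehicle (0.148) than to its own group (0.154). The count of that comparison stayed at 0 without any 1 of its 12 arrays. Since both groups held such arrays, leaving out 1 at a time cannot tell whether the 0 depends on them.

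Regrouping asked only whether chance can be excluded. Each value is the number of 100 splits that gave at least as many genes, the real one included. Against vehicle at 6 h it was 7 for vinblastine 0.5 mg/kg (real 4, highest other 372), 1 for vinblastine 3 mg/kg (2637 and 2464), 100 for vincristine 0.1 mg/kg (0 and 981) and 3 for vincristine 1 mg/kg (373 and 1313). For colchicine it was 2 at 0.2 mg/kg (31 and 147) and 3 at 2 mg/kg (1050 and 1130). Against vehicle at 24 h it was 100 for vinblastine 0.5 mg/kg (0 and 1), 1 for vinblastine 3 mg/kg (1082 and 184), 100 for vincristine 0.1 mg/kg (0 and 2) and 1 for vincristine 1 mg/kg (3433 and 1643). For colchicine it was 100 at 0.2 mg/kg (0 and 3) and 1 at 2 mg/kg (5044 and 4887).

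For dose at 6 h the value was 3 with vinblastine (955 and 1761), 2 with vincristine (317 and 431) and 2 with colchicine (1042 and 1272). At 24 h it was 1 for each, with 620 and 352, 2702 and 1967, and 4686 and 3059. Between compounds at 6 h it was 100 for vinblastine and vincristine (0 and 425), 100 for vinblastine and colchicine (0 and 54) and 100 for vincristine and colchicine (0 and 120). At 24 h these were 1 (532 and 51), 2 (3866 and 4676) and 3 (1117 and 1986). The lower doses of the vinca compounds gave 4 at 6 h (7 and 210) and 100 at 24 h (0 and 1). Over time it was 2 for vinblastine (497 and 1151), 1 for vincristine (1385 and 704), 1 for colchicine (2136 and 981) and 4 for vehicle (1 and 1).

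By this test chance was not excluded for the count of 4 genes with vinblastine 0.5 mg/kg at 6 h. Every split reaches a count of 0, so counts of 0 were not tested. The tubulins among those 4 did not overlap with vehicle, Tuba4a at 554 to 817 against 4730 to 6260 and Tubb4b at 508 to 709 against 2800 to 3990. Several splits gave several times the real count, for vinblastine 0.5 and vincristine 1 mg/kg and for the lower vinca doses at 6 h. Such splits point to some structure of the samples. Where it lies was not tested for these comparisons.

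Outlying distances to the own group were 0.295 for vinblastine 0.5 mg/kg at 24 h replicate 5, 0.565 for vinblastine 3 mg/kg at 6 h replicate 1, 0.309 for colchicine 0.2 mg/kg at 24 h replicate 6 and 0.505 for colchicine 2 mg/kg at 24 h replicate 1. The median intensity was 58.8 for vinblastine 0.5 mg/kg at 24 h replicate 2. The Gapdh 3' to 5' log2 ratio was 0.735 for vinblastine 3 mg/kg at 24 h replicate 4, 0.437 for vincristine 1 mg/kg at 24 h replicate 4 and 0.642 for colchicine 2 mg/kg at 6 h replicate 2. That last array also had the outlying actin ratio of 1.27.

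The actin 3' to 5' log2 ratio also differed between groups at 24 h, a comparison made after the values were seen. It was 0.742 ± 0.0595 in vehicle, 0.903 ± 0.237 with vinblastine 3 mg/kg, 0.901 ± 0.13 with vincristine 1 mg/kg and 0.929 ± 0.101 with colchicine 2 mg/kg, where 5 of 6 arrays lay above the highest vehicle value of 0.828. In the same order the Gapdh ratio was 0.297 ± 0.0372, 0.386 ± 0.172, 0.361 ± 0.0389 and 0.311 ± 0.0363, and the hexokinase ratio 1.2 ± 0.087, 1.27 ± 0.317, 1.48 ± 0.301 and 1.26 ± 0.22. With vincristine 1 mg/kg 4 of 6 arrays lay above the highest vehicle hexokinase ratio of 1.33. Whether RNA integrity bears on the gene counts at 24 h was not tested.

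Tuba4a intensity was outlying at 2960 for vehicle at 24 h replicate 6, 554 for vinblastine 0.5 mg/kg at 6 h replicate 6, 709 for vinblastine 0.5 mg/kg at 24 h replicate 5, 760 for vincristine 0.1 mg/kg at 24 h replicate 5 and 4690 for colchicine 2 mg/kg at 6 h replicate 4. Tubb4b was outlying on the same arrays, in that order at 1880, 508, 514, 716 and 3240, and at 1230 for vinblastine 3 mg/kg at 6 h replicate 1. Rfx2 was outlying at 555 for vincristine 0.1 mg/kg at 24 h replicate 5. Tppp3 was outlying at 1040 for vehicle at 24 h replicate 6, 194 for vinblastine 0.5 mg/kg at 6 h replicate 6, 3000 for vincristine 0.1 mg/kg at 24 h replicate 5, 397 for colchicine 2 mg/kg at 6 h replicate 4 and 367 for colchicine 2 mg/kg at 24 h replicate 1.

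The change differed between 24 and 6 h in 497 genes for vinblastine, 1385 for vincristine and 2136 for colchicine. Among 4961 tested probe sets with no or several gene symbols, 622, 51 and 253 passed at 6 h for the higher doses of vinblastine, vincristine and colchicine, and 267, 921 and 1431 at 24 h. They carry no single gene name and were counted only.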

How the results depend on the processing

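Of 589 values of named genes 0 reversed their direction under any alternative in which they were tested, which was 556 for the stricter filter and 588 for the mean of probe sets. Calls were lost for 82 with only the compared groups fitted, 49 without the 6 arrays ending in _2, 25 without a filter, 20 each with quantile normalization and array weights, and at most 18 otherwise. Leaving out 1 array lost 642 of 7267. Leaving out the 10 arrays was chosen after the data were examined, and the other alternatives before. The cause of each move was not tested.

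Of 30 counts, quantile normalization kept 28 within 1.5 times. It gave 1 gene for vincristine 0.1 mg/kg at 6 h and 4 for vehicle over time. Centring, the stricter filter, the offsets and the trend with robust variances kept all 30. Having no filter gave 1 gene for vinblastine against vincristine at 6 h. The mean of probe sets gave 48 for colchicine 0.2 mg/kg at 6 h, 1 for vincristine against colchicine at 6 h and 0 for vehicle over time. Testing every probe set gave 1 for vincristine against colchicine at 6 h and 7 for vehicle over time.

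Without the 6 arrays ending in _2 the counts were 1314 for vinblastine 3 mg/kg at 6 h, 33 and 142 for dose at 6 h with vinblastine and vincristine, 825 for the vinca compounds at 24 h, 4 for their lower doses at 6 h and 0 for vehicle over time. With only the compared groups fitted they were 958, 230 and 4 for vinblastine 3, vincristine 1 and colchicine 0.2 mg/kg at 6 h, 0 for vinblastine dose at 6 h, and 12 for the lower vinca doses at 6 h. Between compounds at 24 h they were 890, 2057 and 46 for vinblastine and vincristine, vinblastine and colchicine, and vincristine and colchicine, with 0 for vehicle over time.

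Array weights kept 9 of 30. Against vehicle they gave 146 and 2389 for colchicine 0.2 and 2 mg/kg at 6 h. At 24 h they gave 3 and 2403 for vinblastine 0.5 and 3 mg/kg, 53 for vincristine 0.1 mg/kg and 4 for colchicine 0.2 mg/kg. For dose they gave 650 and 2621 at 6 h with vincristine and colchicine, and 1430 and 4579 at 24 h with vinblastine and vincristine. Between compounds they gave 1, 28 and 190 at 6 h, and at 24 h 1503 for the vinca compounds and 2706 for vincristine and colchicine. The lower vinca doses gave 23 and 4 at 6 and 24 h. Over time they gave 1278, 2155 and 3546 for vinblastine, vincristine and colchicine, and 128 for vehicle.

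Leaving out the 10 arrays kept 11 of 30. At 6 h it gave 10 for vinblastine 0.5 mg/kg, 1 and 1392 for vincristine 0.1 and 1 mg/kg, and 166 and 2185 for colchicine 0.2 and 2 mg/kg. At 24 h it gave 1 and 1782 for vinblastine 0.5 and 3 mg/kg and 3 for colchicine 0.2 mg/kg. For dose it gave 1273 and 1715 at 6 h with vincristine and colchicine, and 1251 at 24 h with vinblastine. Between compounds it gave 1, 5 and 82 at 6 h, and at 24 h 1509 for the vinca compounds and 2942 for vincristine and colchicine. The lower vinca doses gave 17 at 6 h. Over time it gave 918 for vinblastine and 9 for vehicle.

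The replicate number as a block gave 2 genes for vehicle over time and kept the other 29 counts. The numbers did not pair the animals: of 156 pairs with the same number 45 correlated over 0.1, and 35 arrays correlated best with their own number. The block ended 1 of 140 list calls, fibroblast and matrix genes with vincristine 0.1 mg/kg at 6 h (0.0598).

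Leaving out 1 array at a time gave ranges of 3 to 6, 1381 to 2982, 0 to 0, 27 to 718, 9 to 80 and 737 to 1620 against vehicle at 6 h, in the order of lower and higher vinblastine, vincristine and colchicine. At 24 h they were 0 to 0, 857 to 1026, 0 to 0, 2977 to 3332, 0 to 0 and 4480 to 5543. For dose the ranges were 189 to 1533, 78 to 655 and 684 to 1600 at 6 h, and 459 to 645, 2250 to 2561 and 4095 to 5338 at 24 h. Between compounds they were 0 to 3, 0 to 0 and 0 to 35 at 6 h, and 249 to 844, 3078 to 4694 and 322 to 2409 at 24 h. The lower vinca doses gave 5 to 10 and 0 to 0. Over time they were 318 to 733, 1043 to 1649 and 1602 to 3042, and 0 to 9 for vehicle.

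With separate sets of 3 vehicle arrays the correlation of changes was 0.71, 0.77 and 0.69 at 6 h and 0.76, 0.61 and 0.85 at 24 h. The mean shared calls were 36, 328 and 18, and 353, 309 and 1803. Without the 10 arrays they were 1074, 1399 and 1116 at 6 h, and at 24 h 1502 for the vinca compounds and 1420 for vinblastine and colchicine.

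Of 140 list calls against vehicle an estimated correlation ended 136, quantile normalization 24, the stricter filter 23 and leaving out the 10 arrays 22. Oxidative phosphorylation with vincristine 1 mg/kg at 6 h turned downward after quantile normalization (0.586), and immediate early genes with colchicine 0.2 mg/kg at 24 h turned downward without the 10 arrays (0.388).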

Other observations

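Folding genes were among the biology not yet described. After vinblastine 3 mg/kg at 6 h 10 of 18 tubulin folding genes rose, with a median log2 change of 0.24, and 4 rose without the 10 arrays. With vincristine 1 mg/kg 0 rose (median 0.16), and 3 without the 10 arrays (median 0.14). With colchicine 2 mg/kg 0 rose with or without them (medians 0.09 and 0.1). This list was written after the tubulin results had been seen.

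The tests behind the explanation in this paragraph were chosen after the fall of tubulins had been seen, with the bound written before their values. Free tubulin is known to speed the decay of the messenger RNA of alpha and beta tubulin, so compounds that release tubulin from microtubules could lower these transcripts and leave those of tubulin folding proteins in place. Folding genes that fell past the threshold numbered 0 in each of the 3 comparisons at 6 h, which fits. The fall of the gamma tubulin Tubg1 with vinblastine 0.5 mg/kg (log2 -1.13 ± 0.21) lies outside that account. RNA decay was not measured, so a loss of transcription stays open.

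Vincristine 0.1 mg/kg left Tuba4a at 5360 ± 411 at 6 h while vinblastine 0.5 mg/kg left 720 ± 87.8. The doses differ 5-fold, and potency was not tested.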
